A study of Mus musculus with 2 samples.

How the data were processed

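H3K9ac chromatin immunoprecipitation sequencing was read from 2 samples of mouse neural tube at embryonic day 14.5, which the labels give as biological replicates 1 and 2 of one group. Per the labels, each sample was a pool of embryos of both sexes, 24 in replicate 1 and 34 in replicate 2, and coordinates are on the mm10 build. The work started from the 4 peak lists deposited with the series. Per the deposited file descriptions, 1 list was made from the alignments of each replicate, 1 from both replicates together (the pooled list), and the replicated list was derived from the pooled list and both replicate lists. The same descriptions list 1 more source file for the replicate 1 and pooled lists than for the replicate 2 list. The aligner, the peak caller, the use of an input control and the overlap rule behind the replicated list were not given in the sources used here.

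Each list is in narrowPeak format. The fold enrichment per peak is the signal value that the authors' peak caller wrote into the deposited lists. It was read here as a linear ratio from its range, because neither the caller nor its unit was given in the sources used here. The authors also gave a -log10 p and a -log10 q per peak, and each deposited list ends just above a -log10 p of 2. The score column of the deposited lists, scaled by the authors within each list, was not used. The summit of each peak is the offset in bp from the peak's start that the authors' caller wrote into the deposited lists. Fold enrichment was used to describe, rank and divide peaks within a list. Replicated peaks carry the pooled list's values, so a gene's values from the replicated list and from each replicate are shown side by side and were not averaged. In the series tables, 0 columns of per-sample values were left unused. Peak lists hold no read totals, so the depth of each sample is unknown, and the precision of a single peak's fold enrichment cannot be given.

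Genes, transcripts and biotypes came from GENCODE release M21, which uses the same assembly. All peak ends were checked against the chromosome lengths of the reference genome and lay within them. Peaks on unplaced contigs, 9 of the replicated list, were left out of the results by location and of the shuffles. They were kept where marked promoters were counted over all genes. Promoter CpG content was the highest observed over expected CpG ratio among a gene's starts, in 1 kb either side. Tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9, with random seed 1.

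Peaks of the replicates were called shared with an overlap of at least 1 bp. Shuffles moved peaks within their chromosome, outside assembly gaps of at least 100 bases, 100 times. The location of a peak was that of its midpoint. A promoter was marked when a replicated peak overlapped 1 kb either side of any annotated start of the gene, and its value was the highest fold enrichment of a peak in that window. Domains were replicated peaks merged across gaps of up to 1 kb. Distal peaks lay more than 2.5 kb from any annotated start and were counted within 50 kb of a gene's starts.

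The 30 gene lists, the tests, the rule for named genes and the first set of alternatives were chosen before the data were examined. Of the list members, 1 had no match in the annotation and was left out, and 1 was matched through a synonym. Marked shares were compared with all other protein-coding genes by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 30 lists and a threshold of 0.05. As an alternative, 10000 lists were drawn from the same 10 bins of CpG content. Domain width was compared by a two-sided permutation test of the median against 100000 random lists of marked genes, adjusted over the 21 lists with at least 5 marked members. Distal peaks were compared by the same number of random lists of protein-coding genes, adjusted over 30 lists. Hox genes were tested by permutation of Spearman's rho between paralog group and being marked or fold enrichment, adjusted over 6 tests, and the X against the autosomes by Fisher's exact test. These tests ask whether a list stands apart in one tissue. Genes are not replicates, neighbours can share a peak or a domain, and some genes belong to several lists. Shares of peaks and genes carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

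Named protein-coding genes followed a fixed rule. They were the 10 with the highest promoter fold enrichment and the 10 in the widest domains, 1 per domain, each with a peak in both replicate lists. From each gene list came the 3 marked members with the highest fold enrichment, and the unmarked members where there were 5 or fewer, or else the 3 written first. Further names were those nearest the 5 widest distal domains and the 5 distal peaks of highest fold enrichment, any Hox gene, and the 5 strongest promoters of each replicate among genes unmarked in the other. Members named to complete a count of 5 or fewer, and other genes outside this rule, were chosen after their values were seen.

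The procedures were tested on simulated data made from the real annotation. All 200 genes touched by 1 base of a peak were called marked, and 0 of 200 missed by 1 base. Of lists of 20 genes given a marked rate of 95%, 90 of 100 were called higher, and of those given 25%, 86 of 100 were called lower, with 4 of 200 unchanged lists called. For domain width, 13 of 20 lists drawn from the wider part of the genes were called and 1 of 20 random lists. For distal peaks, 20 of 20 lists drawn from genes with a distal peak were called and 0 of 20 random lists. Only 5968 protein-coding genes had a distal peak within 50 kb, so success with such lists followed largely from their construction. In the share simulation genes were marked independently, so it does not cover calls that follow CpG content.

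Alternatives were the pooled list, each replicate's list alone, peaks with -log10 p of at least 5 or -log10 q of at least 2, windows of 500 bp and 2 kb, only the outermost start, and the summit in the window. Others were stricter overlaps, equal numbers of top peaks, CpG-matched lists, a background without olfactory and vomeronasal receptors, other gaps between merged peaks, a distal window of 100 kb, a distance of 5 kb and assignment to the nearest start. The alternatives chosen after seeing the data were each domain counted once per list, leaving out the member with the most distal peaks, and a peak needed in both replicate lists.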

Results

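The series profiled H3K9ac, an acetylation of histone H3 found at active promoters and enhancers, by chromatin immunoprecipitation sequencing of mouse neural tube at embryonic day 14.5. The single group held 2 biological replicates, pools of 24 embryos (replicate 1) and 34 embryos (replicate 2) of both sexes. Nothing was compared between conditions, because there was no second group. The 4 deposited peak lists held 68344 peaks for replicate 1, 40209 for replicate 2, 43394 for the pooled reads and 27044 in the replicated list. Peak lists carry no read totals, so the depth of each sample was unknown. Fold enrichment below is the authors' signal value per peak, read as a linear fold from its range, since the peak caller was not given in the sources used here. Where 3 fold enrichments follow a gene, they come from the replicated list, replicate 1 and replicate 2, in that order. The intervals given cover counting error only, and genes are not independent replicates.

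The first comparison asked how far the replicates shared their peaks. Of the replicate 1 peaks, 41.0% overlapped a replicate 2 peak (95% exact interval 40.6 to 41.3), against a mean of 1.83% in 100 shuffles. Of the replicate 2 peaks, 66.9% overlapped a replicate 1 peak (66.4 to 67.3), against 3.01% in shuffles. Sharing rose with enrichment. In the top quintile by fold enrichment 99.6% of replicate 1 peaks and 100% of replicate 2 peaks were shared, and in the lowest quintile 13.8% and 29.5%. Peaks found in a single replicate had a median fold enrichment of 3.18 in replicate 1 and 3.15 in replicate 2, and shared peaks 5.67 and 6.01. Across 23457 shared regions the fold enrichments had a Spearman's rho of 0.876. Replicate 1 listed 1.70 times as many peaks as replicate 2 but covered 1.19 times the length (32.1 against 27.0 Mb). Among peaks with -log10 p of at least 5 it listed 1.11 times as many, and 13.3% of the peaks found in replicate 1 alone reached that level. With -log10 p of at least 5 in both lists, 73.4% of replicate 1 peaks were shared.

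**Figure D1:**
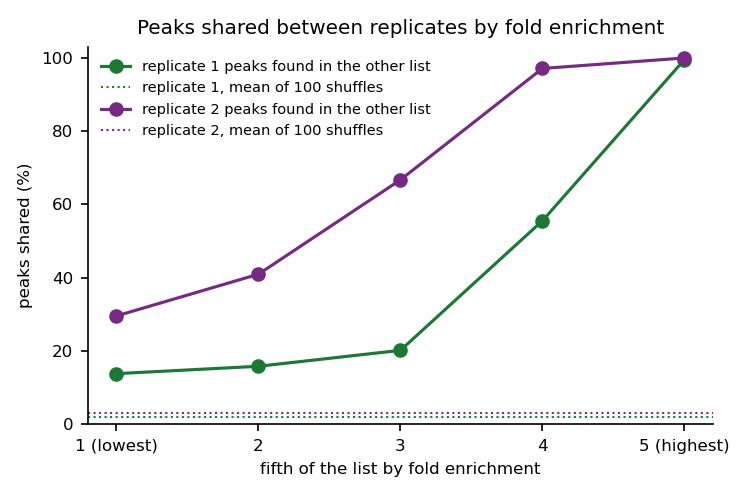
Sharing of H3K9ac peaks between the 2 replicates by fold enrichment: points give the share of peaks that overlap the other replicate's list (percent) and dotted lines the mean of 100 shuffles. The share climbs from 13.8% to 99.6% over the quintiles of replicate 1 and from 29.5% to 100% over those of replicate 2.

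The promoters strongest in one replicate and without a peak in the other were Ttc23 (fold enrichment 14.1) and Tmem88b (13.4) for replicate 1. For replicate 2 they were Sat1 (6.86), a polyamine acetyltransferase, and Cby3 (6.25). All of the 27044 replicated peaks were peaks of the pooled list, and 22912 of them overlapped both replicates' peaks by at least 50% of either length. The other 4132 (15.3%) did not, and had a median fold enrichment of 3.39 against 7.49.

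The next question was where in the genome the mark lay. In the replicated list, 64.9% of peaks (64.3 to 65.5) had their midpoint within 1 kb of a transcript start, 10 times the 6.47% of shuffled peaks. Introns held 19.1% (40.3% shuffled), and stretches between genes 11.6% (49.7% shuffled). The promoter share was 38.3% in replicate 1 and 54.1% in replicate 2 (mean 46.2% ± 11.2, SD, n = 2) and 49.1% in the pooled list. Replicated promoter peaks were wider and more enriched than the others, with a median of 1074 bp and 9.26-fold, against 432 bp and 3.74-fold in introns.

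**Figure D2:**
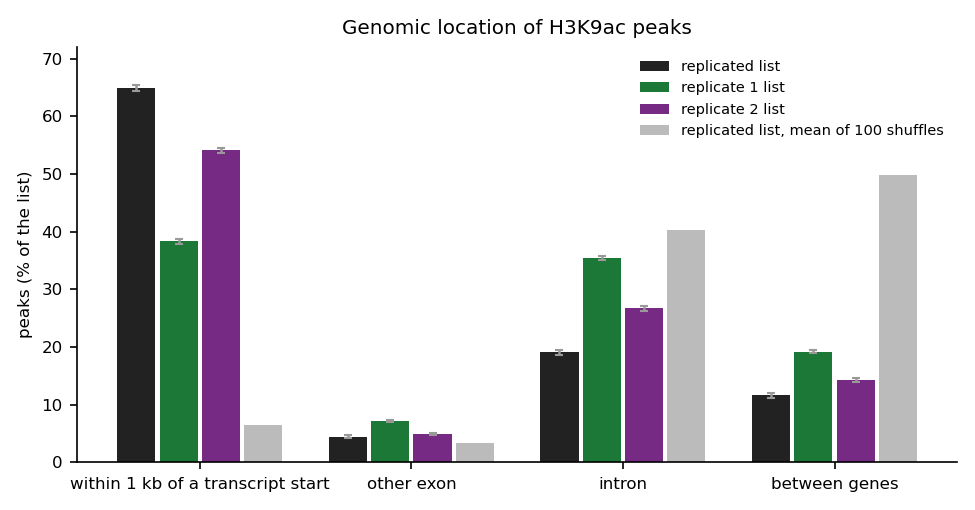
Location of peaks by midpoint (percent of peaks) in the replicated list, each replicate's list and shuffled replicated peaks, with error bars for the 95% exact interval. Promoters hold 64.9% of replicated peaks and 6.47% of shuffled ones.

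A promoter was called marked when a replicated peak overlapped the window of 1 kb either side of any annotated start. Of 22028 protein-coding genes, 13798 (62.6%, 62.0 to 63.3) were marked. The replicates' own lists gave 65.9% and 63.0% (mean 64.5% ± 2.10, SD, n = 2). Marked shares were 33.3% for antisense genes, 13.5% for lincRNA genes and 0.946% for processed pseudogenes. Across protein-coding genes marked in both replicates, promoter fold enrichment had a rho of 0.849 between them.

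The protein-coding promoters with a peak in both replicate lists were ranked by fold enrichment in the replicated list. Dbn1, which encodes the actin-binding protein drebrin, stood highest with fold enrichments of 43.5, 40.9 and 29.9 (chromosome 13, gene at 55473429 to 55488111). It was followed by Tnpo1, a nuclear import receptor (42.1, 41.3 and 31.3), Marcksl1 (40.9, 36.6 and 33.8) and Actb, which encodes beta-actin (40.9, 39.5 and 20.3). Rbm39, Usp22, Hoxd3, Hoxd4, Sp3 and Adnp completed the first 10, at 38.3-fold to 40.5-fold in the replicated list. Hoxd3 and Hoxd4 shared a single peak.

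Domains were replicated peaks merged across gaps of up to 1 kb, and their median width over marked promoters was 1641 bp. The widest 3 at protein-coding promoters covered Hox clusters, with 86877 bp around Hoxb4 (chromosome 11, 96268596 to 96355472), 55698 bp around Hoxc8 and 41970 bp around Hoxa7. Outside the Hox clusters the widest at a protein-coding promoter was 27040 bp at Ebf3, a neuronal differentiation factor (chromosome 7, 137296302 to 137323341). Next among protein-coding promoters came Lhx1 (20816 bp), which specifies spinal interneurons, Nfib (19643 bp), a gliogenic factor, Nr2f2 (18886 bp), Zfhx3 (17610 bp), Lhx5 (17050 bp) and Meis2 (16606 bp).

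Gene lists fixed in advance were then compared with all other protein-coding genes, of which about 62.6% were marked. Two-sided Fisher's exact tests were adjusted by Benjamini-Hochberg over 30 lists. A higher share was marked in 10 lists, a lower share in 10, and 10 passed in neither direction.

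All 20 pan-neuronal genes were marked in the replicated list and in each replicate's list (adjusted exact p = 0.000385). Examples were the neuronal splicing regulator Rbfox3 (fold enrichments 27.3, 25.7 and 20.8), the adhesion molecule Ncam1 (25.3, 22 and 20.8) and Mapt, which encodes tau (24.0, 21 and 18.9). Among radial glia and neural stem cell genes 19 of 20 were marked (adjusted exact p = 0.0032), led by the RNA-binding proteins Msi1 (29.9, 29.4 and 22.7) and Msi2 (21.1, 17.2 and 18). Nr2e1 was the one unmarked. Axon guidance genes were marked in 19 of 20 cases (adjusted exact p = 0.0032), among them the semaphorin receptor subunits Plxna1 (20.9, 19.6 and 18.3) and Nrp1 (19, 16.4 and 15.2), with Robo3 unmarked. With the peak's summit required in the window, the radial glia and axon guidance lists each stood 23.2 points above background (adjusted exact p = 0.0558).

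Spinal neuron identity factors were marked in 26 of 30 cases (adjusted exact p = 0.0111). Foxp1, a motor column factor, had fold enrichments of 20.9, 19.2 and 16.8, and the dorsal interneuron factor Lbx1 18.7, 15.6 and 16.2. Barhl1, Tlx1, Vsx2 and Sim1 were unmarked, each with a peak in replicate 1 and none in replicate 2. The list was marked at 100% in replicate 1 and 80% in replicate 2 (mean 90% ± 14.1, SD, n = 2), and its call was lost without replicate 1 (17.1 points above background, adjusted exact p = 0.0828). The call was also lost at -log10 p of at least 5 (14.6 points, 0.187), with only the outermost start (17.8 points, 0.0927) and with a peak needed in both replicates (18.3 points, 0.0567).

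All 20 Notch pathway genes (adjusted exact p = 0.000385) and all 16 Hedgehog pathway genes (0.00212) were marked. Examples were the Notch ligand Dll1 (20.8, 17.8 and 18.3), the Notch transcription factor Rbpj (18.7, 15.6 and 16.8) and the Hedgehog receptor Ptch1 (21.2, 21.7 and 18.3). All 20 genes of the H3K9 acetylation and deacetylation machinery, among them the bromodomain protein Brd4 (22, 21.7 and 15.5), and all 20 housekeeping genes were marked (0.000385 each). The cell cycle list had 19 of 20 marked (0.0032), with Birc5 at 12.7, 11.3 and 13.7 and Mcm3 unmarked.

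The lists were also set against genes of the same promoter CpG content. Against genes drawn from the same of 10 CpG bins, only the pan-neuronal list stood higher, at 100% against 80.1% expected (adjusted permutation p = 0.0171). The other 9 lists with a higher share lost that call. Their adjusted permutation p ran from 0.0613, for spinal neuron identity factors, which turned to -9.72 points, to 1. The Notch, Hedgehog, H3K9 machinery and housekeeping lists already had 100% marked, against 90.3% to 93.2% expected. At their size the matched test could not have called them higher, so it does not decide whether they stand apart. The radial glia, axon guidance, cell cycle and spinal neuron identity lists had 92.6% to 96.4% expected. Even with every member marked they could not have been called higher, so their lost calls do not decide this either.

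Factors of the forebrain and midbrain were the neural list with the fewest marked promoters, 4 of 20 (adjusted exact p = 0.000628). The 4 were Hesx1 (4.55-fold in the replicated list), Lhx8 (4.20), Eomes (3.21) and Dlx5, the last named after its values were seen to complete the count. Hesx1 had no promoter peak in replicate 1 and Dlx5 none in replicate 2. Foxg1, Emx1 and Emx2, regulators of the telencephalon, had no promoter peak in any of the 4 lists. Of the 16 unmarked members, 8 (50%) had a promoter peak in the list of a single replicate or of the pool. Six6, Rax, Otx1, Vax1 and En2 had one in replicate 1 alone. The share among all unmarked protein-coding genes was 11.9%, but these were not matched for CpG content. CpG matching gave an expected 94.6%, and the list stayed lower (adjusted permutation p = 0.0005, from 1e-04, the smallest the draws can give). Its share was 45% in replicate 1 and 20% in replicate 2, and without replicate 2 the list was -21 points from background (adjusted exact p = 0.084).

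**Figure D3:**
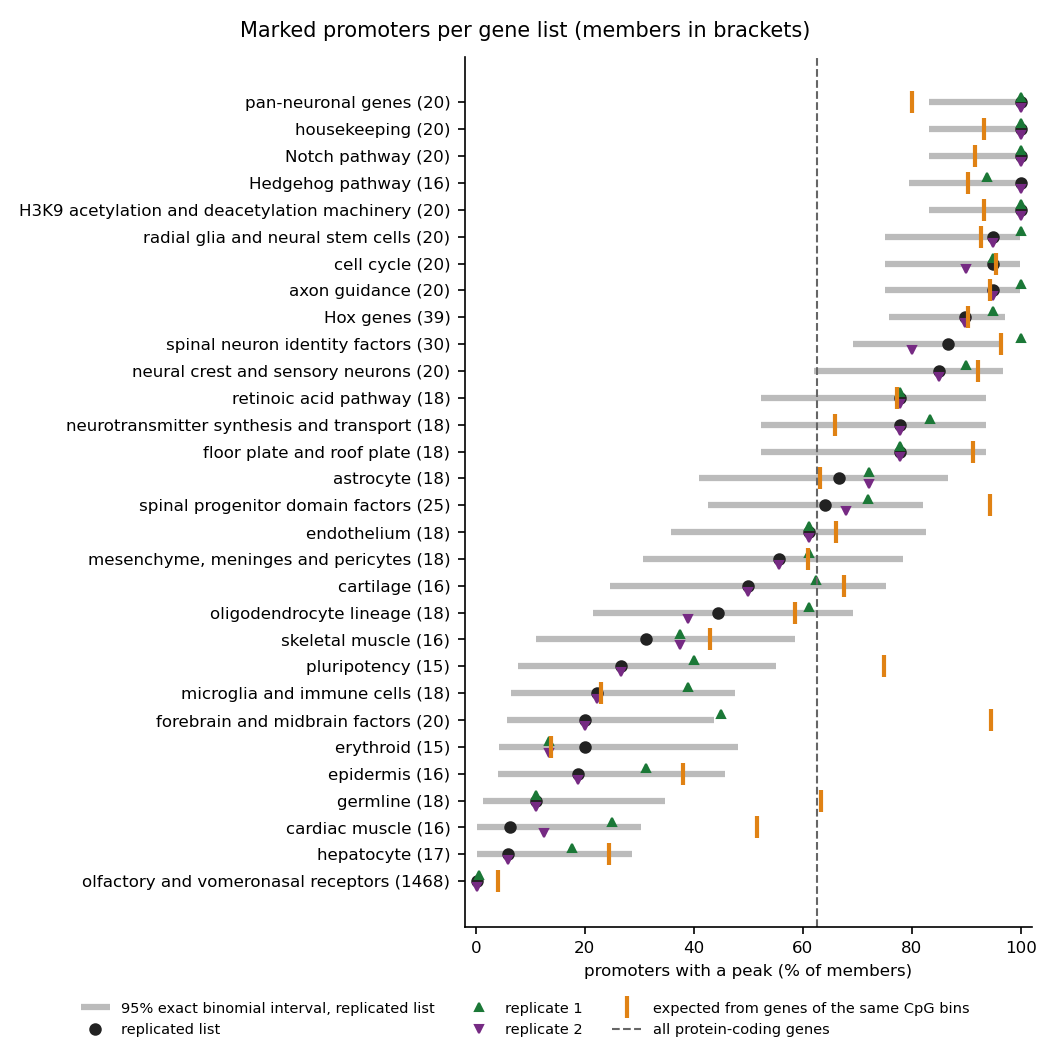
Share of marked promoters in the 30 gene lists (percent of members) with 95% exact intervals, each replicate's share (triangles), the share of all protein-coding genes (dashed line) and the share expected from genes of the same CpG content. Pan-neuronal genes stand at 100% and forebrain and midbrain factors at 20%.

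Spinal progenitor domain factors, which pattern the ventricular zone, were marked in 16 of 25 cases, not different from background (adjusted exact p = 1). Against CpG-matched genes, of which 94.3% were expected to be marked, the list turned lower by the test (-30.3 points, adjusted permutation p = 0.0005). Its highest members were the proneural factor Ascl1 (12.8, 9.78 and 12.4), Irx5 (10.8, 12.3 and 8.41) and Irx3 (10, 10.9 and 7.48), and Atoh1, Gsx2 and Dbx1 were unmarked.

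Markers of most other tissues were seldom marked. The counts were 1 of 17 for hepatocyte genes (adjusted exact p = 2.36e-05), 1 of 16 for cardiac muscle (3.98e-05), 2 of 18 for germline (6.91e-05) and 3 of 16 for epidermis (0.00118). They were 4 of 18 for microglia and immune cells (0.00197), 3 of 15 for erythroid genes (0.00212), 4 of 15 for pluripotency (0.00999) and 5 of 16 for skeletal muscle (0.0251). Of 1468 olfactory and vomeronasal receptors, 2 were marked, Vmn1r4 and Olfr94. The hepatocyte gene marked was Apoh (12.9, 11.8 and 13.1), the cardiac one Ryr2, a calcium channel also used by neurons (16.5, 12.3 and 15.5), and the germline pair Gdf9 and Dazl. Klf1, Nfe2 and Gypa were the marked erythroid genes, Gypa (3.02) without a promoter peak in either replicate's list, and the globin genes Hba-a1, Hba-a2 and Hba-x had no promoter peak in any list. Hba-a1 and Hba-a2, like many receptor genes, are near-identical copies, and how reads that fit several places were treated was not given in the sources used here. Marked epidermal genes were Krt10, Krt1 and Grhl3. Named after their values were seen, to complete counts of 5 or fewer, were Aif1 beside Hexb, Irf8 and Tmem119 (microglia), Lin28a beside Klf4, Esrrb and Tfcp2l1 (pluripotency), and Des and Tnni1 beside Actn2, Ckm and Myod1 (muscle). Of these, Tmem119 and Des had no promoter peak in replicate 2.

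Against CpG-matched genes the cardiac (6.25% marked, 51.6% expected), pluripotency (26.7%, 74.9%) and germline (11.1%, 63.4%) lists were still lower (adjusted permutation p = 0.0005 each). The receptors were too (0.0005), but by far less than against all genes, with 0.136% marked and 4.08% expected, where the share of other genes was 67.1%. The erythroid list turned to 6.21 points above the matched share (0.869), and microglia (1), skeletal muscle (0.373), hepatocyte (0.0613) and epidermis (0.0642) lost their calls. The pluripotency call was lost without replicate 2 (-26.0 points, 0.0785) and in the pooled list (-24.8 points, 0.0864). The skeletal muscle call was lost without replicate 1 (-25.5 points, 0.064), with a window of 2 kb (-25.9 points, 0.0579) and with the outermost start (-27.6 points, 0.061).

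Further lists passed the test in neither direction. Marked members numbered 17 of 20 for neural crest and sensory neurons (adjusted exact p = 0.0557), and 14 of 18 each for neurotransmitter synthesis and transport, floor plate and roof plate, and the retinoic acid pathway (0.273 each). They numbered 12 of 18 for astrocytes (0.87), 11 of 18 for endothelium (1), 10 of 18 for mesenchyme, meninges and pericytes (0.697), 8 of 18 for the oligodendrocyte lineage (0.194) and 8 of 16 for cartilage (0.358). Without replicate 2 the neural crest list was 24.1 points above background (adjusted exact p = 0.0481). The vesicular glutamate transporter Slc17a6 had fold enrichments of 17.1, 15.6 and 19.2, and the glycine transporter Slc6a5 14.2, 13 and 11.5. The catecholamine and serotonin enzymes Th, Dbh and Tph2 were unmarked. Nfib (24.8, 22.1 and 20.2) and Nfia (22.2, 20.3 and 17.1) led the astrocyte list, while Gfap, Aqp4 and Aldh1l1, markers of mature astrocytes, had no promoter peak in any list. The oligodendrocyte factors Olig1 and Olig2 had peaks in replicate 1 (3.62-fold and 3.92-fold) and the pooled list, and none in replicate 2.

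Hox genes, which set position along the body axis, were marked in 35 of 39 cases (adjusted exact p = 0.000628). The unmarked ones were Hoxa13, Hoxb13, Hoxd12 and Hoxd13, which belong to the last paralog groups. All 33 genes of paralog groups 1 to 11 were marked, with 1 of 2 in group 12 (Hoxc12) and 1 of 4 in group 13 (Hoxc13). Across genes, paralog group and being marked had a Spearman's rho of -0.505 (permutation p = 0.00021, adjusted over 6 tests 0.00063). Paralog group and fold enrichment had a rho of -0.42 (permutation p = 0.00824, adjusted 0.0103). Unmarked genes count as 0 in it, so it partly repeats the test of being marked, and group 1 ran against it, with a median of 5.69-fold against 9.65 to 36.3 in groups 2 to 11. The rho for being marked was -0.332 in replicate 1 (permutation p = 0.0307) and -0.505 in replicate 2. A single replicated peak of 78903 bp (chromosome 11, 96268596 to 96347498) reached the promoters from Hoxb3 to Hoxb9, where the widest peak was 28109 bp in replicate 1 and 65155 bp in replicate 2. Genes under that peak share its fold enrichment of 36.3, so neighbouring genes are not separate measurements. With the summit required in the window, the Hox list stood at -5.42 points from background (adjusted exact p = 0.59) and both trends missed the threshold (rho -0.237, permutation p = 0.148, and -0.241, permutation p = 0.138).

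**Figure D4:**
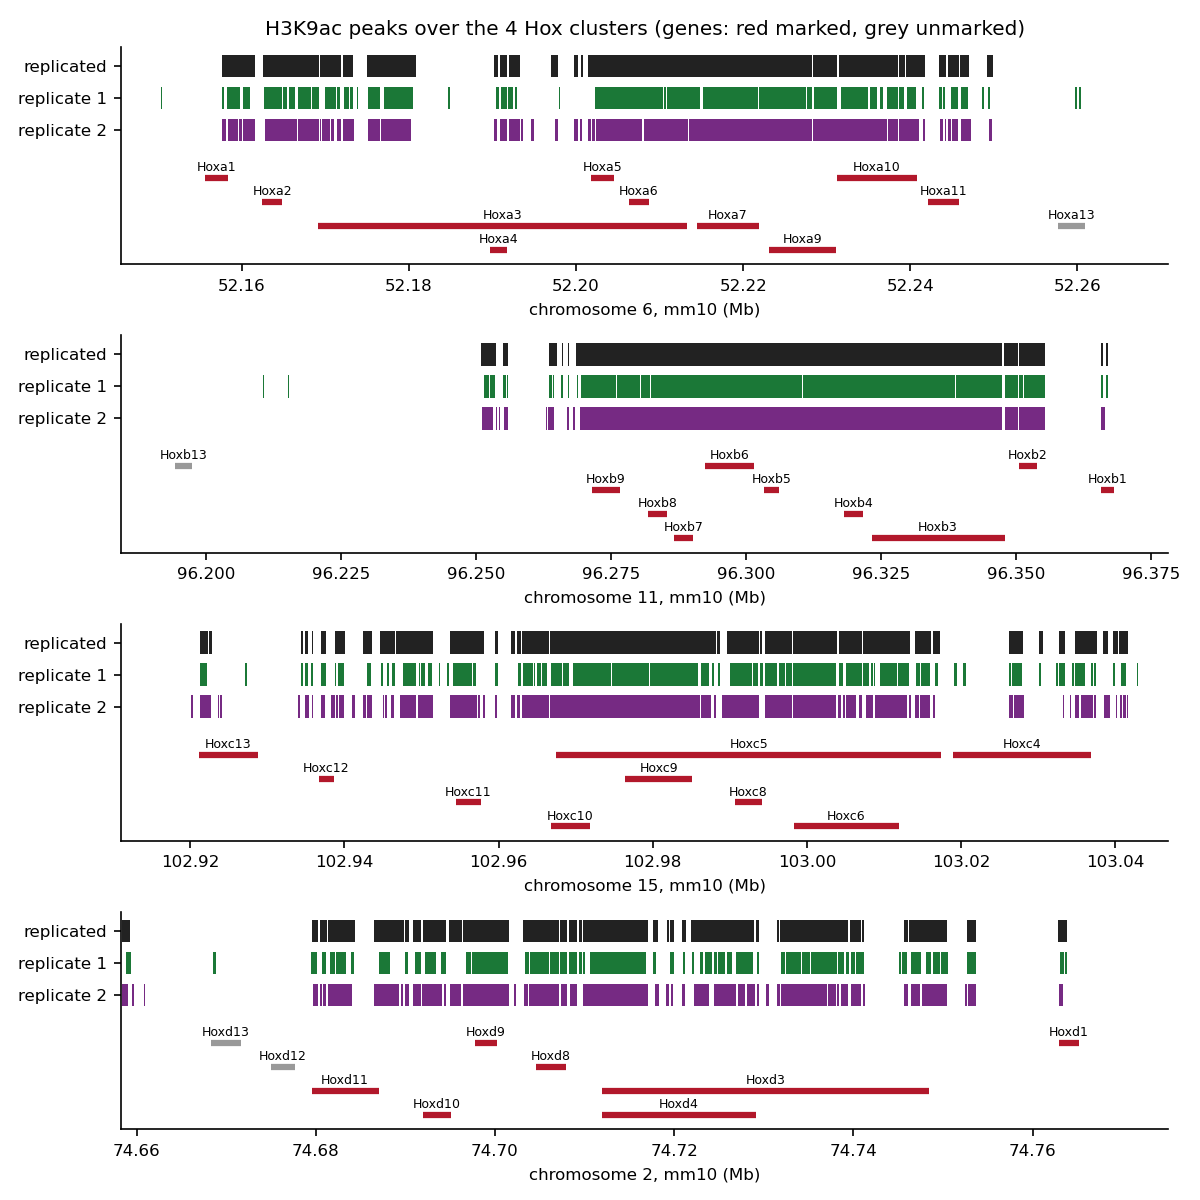
H3K9ac peaks over the 4 Hox clusters (position in Mb) in the replicated list and in each replicate, with the Hox genes below, marked ones in red and unmarked ones in grey. The replicated peak of 78903 bp spans Hoxb3 to Hoxb9, and Hoxa13, Hoxb13, Hoxd12 and Hoxd13 have no replicated promoter peak.

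Promoter domains were wider than those of random marked genes in 7 of 21 lists with at least 5 marked members. The median width was 4009.5 bp for pan-neuronal genes, 3879 bp for axon guidance and 3441 bp for radial glia (adjusted permutation p = 0.000105 each, from 2e-05, the smallest that the permutations can give). Astrocyte genes had 3030 bp (0.00224), Notch pathway genes 2534 bp (0.00492) and spinal neuron identity factors 2216.5 bp (0.031). Hox genes had 41970 bp (0.000105), with many members in one domain. The 5 marked skeletal muscle genes had narrower domains, 359 bp (0.000504). For spinal neuron identity factors the difference from random lists was 576 bp. It lost its call without replicate 2 (345.5 bp, adjusted permutation p = 0.182) and with CpG-matched lists (297 bp, 0.279), and turned to -436.5 bp when no gaps were merged. The Notch list also lost its call with no gaps merged (294 bp, 0.238). Housekeeping genes (2198 bp, 0.0766) were called wider without replicate 1 (0.0311), without replicate 2 (0.0102) and with gaps of up to 3 kb merged (0.00667), where spinal progenitor factors (0.0147) and neurotransmitter genes (8.4e-05) were too. With no gaps merged 5 lists were wider and 5 narrower, the latter skeletal muscle, spinal progenitor and spinal neuron identity factors (adjusted permutation p = 0.00739 each for the last 2), mesenchyme (0.00709) and the cell cycle (0.00021). Without replicate 2, 7 were wider and 4 narrower, because the forebrain and midbrain (0.000104), microglia (0.00342) and receptor lists (0.00026) then had at least 5 marked members.

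**Figure D5:**
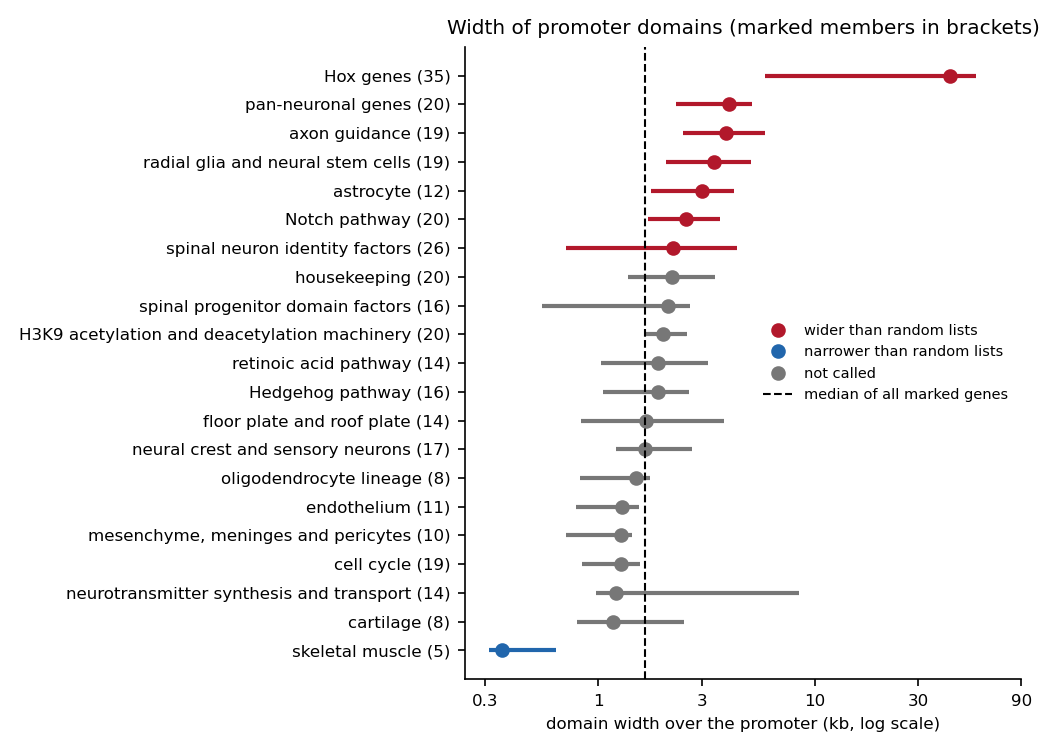
Width of promoter domains by gene list (kb, log axis): dots are medians over marked members, lines run from the first to the last quartile bound, and the dashed line is the median of all marked promoters (1641 bp). Medians are 4009.5 bp in pan-neuronal genes and 359 bp in skeletal muscle genes.

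Peaks far from promoters made up 23.9% of the replicated list (6457 peaks more than 2.5 kb from any start). The widest distal domain, of 17017 bp (chromosome 15, 85665444 to 85682460), lay over the noncoding gene Lncppara, 52.5 kb from the nearest protein-coding start, that of Ppara. Its fold enrichments were 27.3, 29.4 and 23.6. The next were 6428 bp over the noncoding gene Gm30340 and 6398 bp over Pantr1, near the neural factor gene Pou3f3. Other distal peaks of high enrichment had Chd2 (23.9, 20.5 and 12), Cbx8 (23.8, 23.9 and 16.5) and Ddit4 (23.0, 18.1 and 21.1) as their nearest coding genes.

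Distal peaks within 50 kb averaged 0.504 per protein-coding gene and were more frequent by permutation test near 7 of 30 lists. The means were 2.56 for Hox genes (adjusted permutation p = 0.0003), 1.70 for radial glia (0.0228), 1.60 for the Notch pathway (0.028), 1.56 for astrocytes (0.0319) and 1.55 for pan-neuronal genes (0.0301). Spinal neuron identity factors averaged 1.47 (0.0202) and the H3K9 acetylation and deacetylation machinery 1.45 (0.0319). Olfactory and vomeronasal receptors had fewer, 0.0422 (0.0003). Without the member with the most distal peaks, Hox genes were the 1 list called with more and the receptors the 1 list called with fewer. The H3K9 machinery list, without Ncor2, turned to -0.136 from the mean. Neighbouring Hox genes count the same distal peaks within 50 kb, so leaving out 1 gene cannot decide whether the Hox list stands apart. The permutation p of the Hox list takes no account of this sharing. With peaks more than 5 kb from a start, 0 lists had more (adjusted permutation p from 0.0594 to 0.157 for the 7), and 1 list still had fewer. When each peak was assigned to its nearest coding start, the Hox list lost its call (0.498), the machinery list too (0.0746), and axon guidance (0.019) and spinal progenitor factors (0.0202) gained one. The machinery list also lost its call within 100 kb (adjusted permutation p = 0.104) and without replicate 1 (0.0514). Without replicate 2 radial glia (0.0617) and astrocytes (0.0563) lost theirs, and floor plate and roof plate (0.0331) and the retinoic acid pathway (0.0428) gained one.

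X-linked promoters were less often marked than autosomal ones. On the X 441 of 948 protein-coding genes were marked (46.5%), against 64.2% on the autosomes (two-sided Fisher's exact p = 3.69e-27). The shares were 47.6% against 67.6% in replicate 1 and 46.3% against 64.5% in replicate 2. The X held 3.98 replicated peaks per Mb and the autosomes together 10.7, with a range of 7.03 to 19 between autosomes. The lowest marked share of any autosome was 51.8%. Autosomal genes drawn from the same CpG bins as the X-linked ones had 50.6% marked, and the X-linked share differed from that by -4.11 points.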

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

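Tests with each domain counted once, without the member with the most distal peaks, or with a peak needed in both replicate lists were chosen after seeing the data. No paired analysis was possible because there was only 1 group. Read depth is unknown, so it sets no stated limit here, and with 2 replicates a result without one of them rests on a single list. The cause of the changes below was not tested unless one is named.

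The share of replicate 1 peaks found in replicate 2, and of replicate 2 peaks found in replicate 1, was 35.3% and 55.9% with an overlap of at least 50% of the peak's own length and 27.8% and 47.3% with reciprocal overlap, which by construction can only lower it. It was 73.4% and 80.4% at -log10 p of at least 5, 61.5% and 78.0% at -log10 q of at least 2, 78.4% and 79.1% for the top 5000 peaks, 87.4% and 89.05% for the top 10000, 84.4% and 84.4% for the top 20000, and 60.3% and 60.4% for lists of equal length. Replicated peaks overlapping both replicate lists made up 84.7% with at least 50% of either length, against 85.2%.

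Marked protein-coding promoters made up 64.7% in the pooled list, 63.0% to 65.9% without one replicate, and 58.9% with the outermost start alone, which offers fewer starts. Peaks within 1 kb of a start made up 49.1% of the pooled list and 38.3% to 54.1% without one replicate.

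Lists called higher numbered 9 to 11 without one replicate, and lists called lower 8 to 9. With CpG-matched lists 1 was higher and 6 were lower. Lists with every member marked and an expected share of 90.3% to 93.2% could not be called higher there. Nor could the radial glia, axon guidance, cell cycle and spinal neuron identity lists, with 92.6% to 96.4% expected. The matched difference reversed for spinal progenitor domain factors (-30.3 points), spinal neuron identity factors (-9.72), erythroid genes (6.21), the cell cycle (-0.518) and Hox genes (-0.552). Floor plate and roof plate (77.8% marked, 91.2% expected) and neural crest (85%, 92.2%) also turned below the matched share, but were called in neither setting. The Hox list also reversed with the summit in the window (-5.42 points), where its rho weakened to -0.237 for being marked and -0.241 for fold enrichment. A wide peak has 1 summit, which by construction lies in few of the windows it covers. Over all alternatives, the lists' marked shares kept their side of the threshold in 331 cases, lost the call in 22, gained it in 1 and reversed in 6. A change of direction counted as reversed only where either value passed the threshold, so the 331 include changes of direction between uncalled values.

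Lists with narrower domains numbered 5 with no gaps merged and 1 to 4 without one replicate. With no gaps merged, spinal progenitor (-540.5 bp) and spinal neuron identity factors (-436.5 bp) reversed, and with gaps of up to 3 kb merged neurotransmitter genes did (2863 bp). Lists with more distal peaks numbered 0 beyond 5 kb from a start and 1 without the member with the most, where the H3K9 machinery list reversed (-0.136 per gene). Other width results were unchanged in call in 114 cases, weaker in 3 and stronger in 6, and distal results in 157, 18 and 4. Among named promoters, 2008 results kept their marked state, 57 lost it and 45 gained it. The X-linked share stayed below the autosomal one past the threshold in all 9 alternatives, from -17.2 to -20.0 points. CpG matching was not among these 9, and with it the difference was -4.11 points.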

Other observations

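All values in the next paragraph were chosen after seeing the data, as were 4 of the tests that follow: random background calls and broken wide regions for the peak numbers, and peaks just outside the window and peaks lost by the replication rule for the forebrain list.

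The most enriched peak of the replicated list lay at the noncoding gene 1810026B05Rik, with fold enrichments of 46.8 (replicated), 46.4 (replicate 1) and 40.6 (replicate 2). Of 22 microRNA genes of the Mir9, Mir124a, Mirlet7, Mir99, Mir100 and Mir125b families looked up, 11 lay in a domain and 11 in none. Mir9-2 lay in a domain of 29386 bp over the noncoding gene C130071C03Rik (chromosome 13, 83713571 to 83742956), Mir9-1 in 24704 bp and Mir9-3 in 17061 bp. Mir124a-2 lay in 17067 bp, Mir124a-1 in 15485 bp and Mir124a-3 in 7732 bp. Of all 2207 annotated microRNA genes, 221 (10%) lay in a domain. Mir125b-1 lay in 12218 bp, Mir125b-2 in 6036 bp, Mir99b and Mirlet7e in one of 4881 bp and Mirlet7i in 4129 bp. Those in none were Mirlet7a-1, Mirlet7a-2, Mirlet7b, Mirlet7c-1, Mirlet7c-2, Mirlet7d, Mirlet7f-1, Mirlet7f-2, Mirlet7g, Mir99a and Mir100. This look-up covers the microRNA gene itself and not a host gene's promoter. The noncoding gene Mir99ahg, whose span holds Mir99a and Mirlet7c-1, had a domain of 4676 bp at one end. At 1513 genes with a single start, the summit of the strongest promoter peak lay downstream of the start in 81.4% (95% exact interval 79.4 to 83.3), at a median offset of 214 bp. The share was 78.5% in replicate 1 and 79.1% in replicate 2.

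Replicate 1 listed more peaks than replicate 2. Most of the excess was of weak peaks, since the ratio of 1.70 fell to 1.11 among peaks with -log10 p of at least 5. Background calls spread at random along the chromosomes were argued against as the source of all peaks found in replicate 1 alone. Of those peaks 17.1% lay within 1 kb of a start, 2.52 times the highest of 100 shuffles. The shuffles were not matched for GC content, so the test cannot exclude background that favours promoters. Wide regions of replicate 2 broken into several calls were argued against as the main source, since replicate 1 peaks beyond the first over the same replicate 2 peak numbered 4534, which is 16.1% of the difference of 28135, under the bound of 25%. This test replaced one on peaks found in replicate 1 alone, 18.5% of which lay within 1 kb of a replicate 2 peak, because such peaks cannot be pieces of a replicate 2 peak. With these added the share is 42.7%, so pieces at the edges of replicate 2 peaks stay open as part of the source. A GC bias of replicate 1 may contribute and stays open: distal peaks of replicate 1 alone had a median GC content 2.11 points above those of replicate 2 alone, between the bounds of 2 and 5 points. Read depth and the additional source file of replicate 1 were not tested, and the design offers no biological group to compare.

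Forebrain and midbrain factors were seldom marked. CpG-poor promoters do not account for this, since the share differed by -74.6 points from that of genes in the same CpG bins. Peaks just outside the window were found at Rax and Tbr1 alone, 12.5% of the 16 unmarked members. The replication rule may have removed part of the peaks: 8 of the 16 (50%) had a promoter peak in another list, which met the bound of 50% first set for this explanation. A second bound was added after that result was seen, and with these 8 counted as marked the share of 60% still differed by -36.3 points from the 96.3% expected, so the rule does not account for the whole gap. The anatomical extent of the dissected tissue was not tested, and the biological reading remains a hypothesis.

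X-linked promoters were less often marked. Low CpG content accounts for much of the gap but not all of it, since within CpG bins a difference of -4.11 points (SD of draws 0.946) was left. Multicopy gene families were approximated by the leading letters of the gene symbol. Among genes whose symbol stem had fewer than 3 members on their chromosome, the difference was -3.01 points (SD 1.21). These were 56.4% of X-linked and 61.9% of autosomal genes. Families by that stem thus did not account for the whole remainder. A shared stem is not the same as a multicopy family, so a part due to such families stays open. Fewer active copies of the X in pools of both sexes could contribute, since marked X-linked promoters had a median fold enrichment of 7.49 against 10.7 in matched autosomal ones (difference -3.21, SD 0.352). This is a hypothesis, because no pool of one sex was compared.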
